A study of Arabidopsis thaliana with 6 samples.

How the data were processed

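RNA-seq libraries of whole seedlings grown on medium with 1% sucrose were compared between wild type and the nup50c mutant, 3 libraries each. Per the labels' protocols, total RNA came from about 50 mg of 9-day-old seedlings and the libraries kept strand. The series' design text names paired reads of 150 nt. Groups were taken from the sample titles. The mutant titles carry a number after a hyphen, which was read as the replicate because the design text speaks of triplicates and the genotype label gives a single mutant. Such numbers can also name alleles, and in that case the nup50c means, SDs and p-values would cover differences between alleles as well as between samples. Nothing in the labels says that the replicates came from separately grown seedlings, so p-values measure the spread between these samples, which may be technical.

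The authors deposited a table of whole-number counts per gene and a table of FPKM. The submitters' processing notes name HISAT2 2.0.4, HTSeq 0.6.1p1 and the genome build TAIR10, with no role or order. Which program wrote either table, whether counting used strand and which total the deposited FPKM were divided by are not given in the sources used here. The deposited counts hold 30865 genes, of which 30645 were matched by locus to the TAIR10.1 annotation, which supplied symbols, descriptions and positions. Symbols of genes in the lists are those written with the lists. No coordinate was taken from the deposited tables.

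The low counts are unusual. Of 185190 values 57420 are 0 and 40 are 1, and 654 genes are at 0 in exactly 1 library, 158 of them with a median above 60 counts. An FPKM above 0 stands beside 1001 of the counts of 0. A 0 was therefore treated as possibly a failed estimate. Named genes at 0 throughout one group are given as listed at 0, without a fold and for some with counts per library. List tests and list means kept members with a 0. Among them were 6 of 30 salicylic acid, 3 of 26 iron, 2 of 21 flavonoid and 10 of 25 mitochondrion-encoded genes. The mutated gene was taken as AT4G11790, the locus written for NUP50C beforehand, since the annotation gives no locus that symbol.

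Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr (at least 10 counts, 15 in total), libraries were scaled by TMM, and the robust quasi-likelihood F test compared the groups with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, without a fold minimum, over 21158 genes. The biological coefficient of variation was 22%. Values are TMM-normalized CPM with the SD over 3 libraries, and the standard error of a log2 fold change was derived from the moderated F. Within-group pairs of libraries differed by more than counting noise (chi-square per gene 14.7 to 30.1), so none was counted as a duplicate. Totals ran from 33273007 to 39574236 counts.

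Gene lists were written before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, over 38 lists with at least 3 tested members. They cover the NUP50 and RanBP1 family, the nuclear pore complex, nuclear transport receptors and Ran, mRNA export and miRNA processing, photosynthesis, chlorophyll biosynthesis, light signalling, the circadian clock, flowering time, hormones, nutrients, stresses, cell cycle and DNA damage, ribosomal proteins, organelle genomes, and markers of stomata, vasculature, root tissues and root hairs. Lists of seed and of flower markers had too few tested members and gave no test. Ribosomal protein genes were split by 60S or 40S in the description, so the other list also holds cytosolic proteins described without these words. Of the listed members 6 were dropped because the annotation gives the symbol to another locus, and 24 were not tested because the count table used here does not list them. Camera called 14 lists, 3 higher and 11 lower. With an estimated correlation 0 were called (lowest adjusted p = 0.29). That setting also uses the few degrees of freedom left by 6 libraries, so its p-values do not reflect the correlation alone. With fry, which tests each list against no change, 5 were called.

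The named genes follow a rule set at the same time: the NUP50 and RanBP1 family; the 12 largest fitted rises and 12 largest falls among called nuclear genes with at least 1 CPM in the higher group and no overlap between groups; and the 3 members with the smallest p of each list with a called member or a camera call. Other called list members (such as *LHY*, *TOC1*, *ELF3*, *GRP7*, *RBCS2B* and *GUN5*), members named for contrast (*RBCS1A*, *RCA*) and the largest changes among called genes above 0 in every library were chosen after their values were seen. Of 120 named genes with a position, 36 overlap another annotated gene, 1 of them on the same strand.

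The test was checked on 10 simulated count sets with the real means, dispersions and library sizes, each with 200 genes changed. The changed genes had a mean of at least 1 CPM, so recovery below that level was not measured. Of genes changed 1.5-fold 27.8% were recovered, of those changed 2-fold 64.6% and of those changed 4-fold 86.4%, over 20777 to 20808 genes tested. Of 1349 simulated calls 11.9% were false (7.1% to 16.7% per set), and 67 of the 160 false calls fell on genes listed at 0 in some library. A changed list was called in 10 of 10 sets and 0 of 370 unchanged lists. Every member of the changed list was raised in nup50c, so its recovery says nothing about lists with partial or mixed shifts. The simulated genes varied independently of each other. These list values therefore say nothing about false calls of lists whose members vary together.

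Alternatives set beforehand were RLE factors, library sizes without the 2 genes over 1% of any library and without organelle genes, no filter, at least 10 counts in all 6 libraries, DESeq2 1.42.0, limma-trend on log2(FPKM + 1), with and without a filter, and on log2(FPKM + 0.1) (3 FPKM settings), a 2-fold minimum, the replicate number as a block, and leaving out each library. Restriction to genes above 0 in all 6 libraries and offsets for GC content and exonic length were added after seeing the data. Permutation tests of positions were run in R, and summaries and figures were made in Python 3.11.15. The 1968 genes that only the FPKM table of 32833 genes holds did not enter the main test.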

Results

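Messenger RNA was profiled in whole 9-day-old seedlings of *Arabidopsis thaliana*, the thale cress. The 6 libraries fell into 2 groups of 3, wild type (the accession Col-0) and the nup50c mutant, whose numbered samples were read as replicates although the numbers could also name alleles. NUP50 proteins belong to the nuclear pore, the channel between nucleus and cytoplasm. The count table summed to 35116694, 36012916 and 39574236 counts in the wild-type libraries and to 34400014, 36984121 and 33273007 in the nup50c libraries. The first principal component of the log2 values held 30.6% of the variance and separated the groups. The second held 23.8% and set nup50c replicate 3, at -83.6, apart from the other libraries, which lay between -4.9 and 31.5.

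The comparison asked which transcripts differ between nup50c and wild-type seedlings. In nup50c, *NUP50C* itself was 2.80-fold lower, and genes of the morning phase of the circadian clock (*CCA1*, *LHY*, *LNK2*, *COL1*) fell, as did 13 genes of the light-harvesting antenna. The clock genes *TOC1*, *ELF3* and *GRP7* rose. Genes of iron uptake (*FRO2*, *IRT1*, *CYP82C4*) and of light signalling (*ELIP1*, *ELIP2*, *HYH*) fell. Harvest times of the groups are not given in the sources used here. A difference in time of day at harvest therefore cannot be told apart from an effect of the genotype on these genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 236 genes were higher and 247 lower in nup50c out of 21158 tested, and 28 of the higher and 93 of the lower genes had a fitted change of 2-fold or more. These include 8 higher genes listed at 0 in all wild-type libraries and 24 lower genes listed at 0 in all nup50c libraries, whose fitted changes depend on values that can be failed estimates. The counts of higher and lower genes were 43 and 65 without wild-type replicate 1, 68 and 98 without wild-type replicate 2, 155 and 216 without wild-type replicate 3, 140 and 125 without nup50c replicate 1, 54 and 79 without nup50c replicate 2, and 172 and 266 without nup50c replicate 3.

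The transcript of *NUP50C* (AT4G11790) was measured at 31.7 ± 3.53 CPM, TMM-normalized, in wild type and 11.3 ± 2.00 in nup50c (SD, n = 3 each). The single libraries held 1255, 1100 and 1142 counts in wild type and 469, 376 and 336 in nup50c. The log2 fold change was -1.49 (SE 0.15, edgeR adjusted p = 0.00293). In the TAIR10.1 annotation the gene lies on chromosome 4 from 7090313 to 7093492, on the plus strand, and is described as a protein with a pleckstrin homology domain. AT4G11800 overlaps it on the other strand, and whether counting used strand is not given in the sources used here. The related genes *NUP50A* (log2 fold change 0.08, adjusted p = 0.82), *NUP50B* (0.01, 0.99), *RANBP1A* (-0.00, 0.98), *RANBP1B* (-0.13, 0.41) and *RANBP1C* (-0.18, 0.47) did not pass the edgeR test. The list of these 6 genes, which includes *NUP50C* itself, passed camera downward (adjusted p = 0.0171; adjusted p = 0.55 with an estimated correlation) at a median of -0.07, with 2 members above 0. *NUP50C* was the 1 member called over all genes and the 1 adjusted over the list alone. The camera call of the list was lost without wild-type replicate 3 (adjusted p = 0.0798), without nup50c replicate 3 (adjusted p = 0.134) and in the 3 FPKM settings (adjusted p = 0.142 to 0.152).

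**Figure D1:**
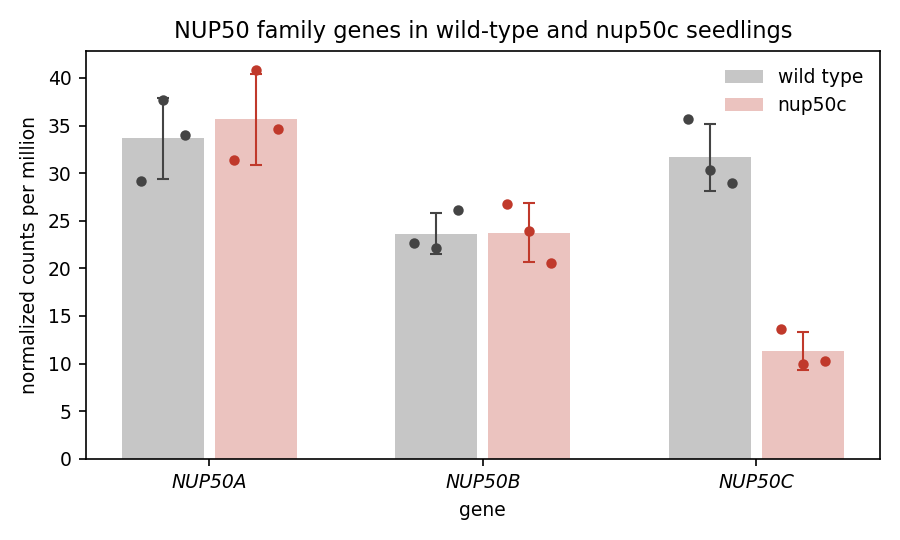
Normalized CPM (vertical axis) of *NUP50A*, *NUP50B* and *NUP50C* in 3 wild-type and 3 nup50c libraries; bars are means, error bars SD and points single libraries. *NUP50C* averages 31.7 in wild type and 11.3 in nup50c with no overlap of libraries, while the groups overlap for *NUP50A* and *NUP50B*.

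Of 28 measured genes of the circadian clock list, 8 fell, 3 rose and 17 did not pass the edgeR test. Adjusted over the list alone, 10 fell and 8 rose. *CCA1*, a MYB transcription factor of the clock's morning loop, went from 73.0 ± 9.28 to 25.7 ± 1.89 CPM (SD, n = 3 each; log2 fold change -1.50, SE 0.11, adjusted p = 0.000833). Its partner *LHY* fell by 1.60 on the log2 scale (SE 0.13, adjusted p = 0.00208). *LNK2*, a coactivator in the clock, fell by 1.42 (adjusted p = 0.000833) and *COL1* by 2.14 (adjusted p = 0.00126). *RVE8*, *COL2*, *LNK1* and *RVE1* completed the falling members. *TOC1*, an evening repressor of *CCA1* and *LHY*, rose from 72.3 ± 9.18 to 118.7 ± 8.03 CPM (log2 fold change 0.71, adjusted p = 0.00951). *ELF3*, of the evening complex, rose by 0.70 (adjusted p = 0.00299), and *GRP7*, an RNA-binding protein under clock control, by 0.60 (adjusted p = 0.0414). The call of *GRP7* was lost without any single library except wild-type replicate 2 (highest adjusted p = 0.150), and that of *RVE1* without wild-type replicate 1, wild-type replicate 3 or nup50c replicate 2 (highest adjusted p = 0.107). The list passed camera downward (adjusted p = 1.33e-06; adjusted p = 0.29 with an estimated correlation) at a median of -0.05, with 13 members above 0 and 15 below, and this call was lost in the 3 FPKM settings (adjusted p = 0.0618 to 0.0655).

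**Figure D2:**
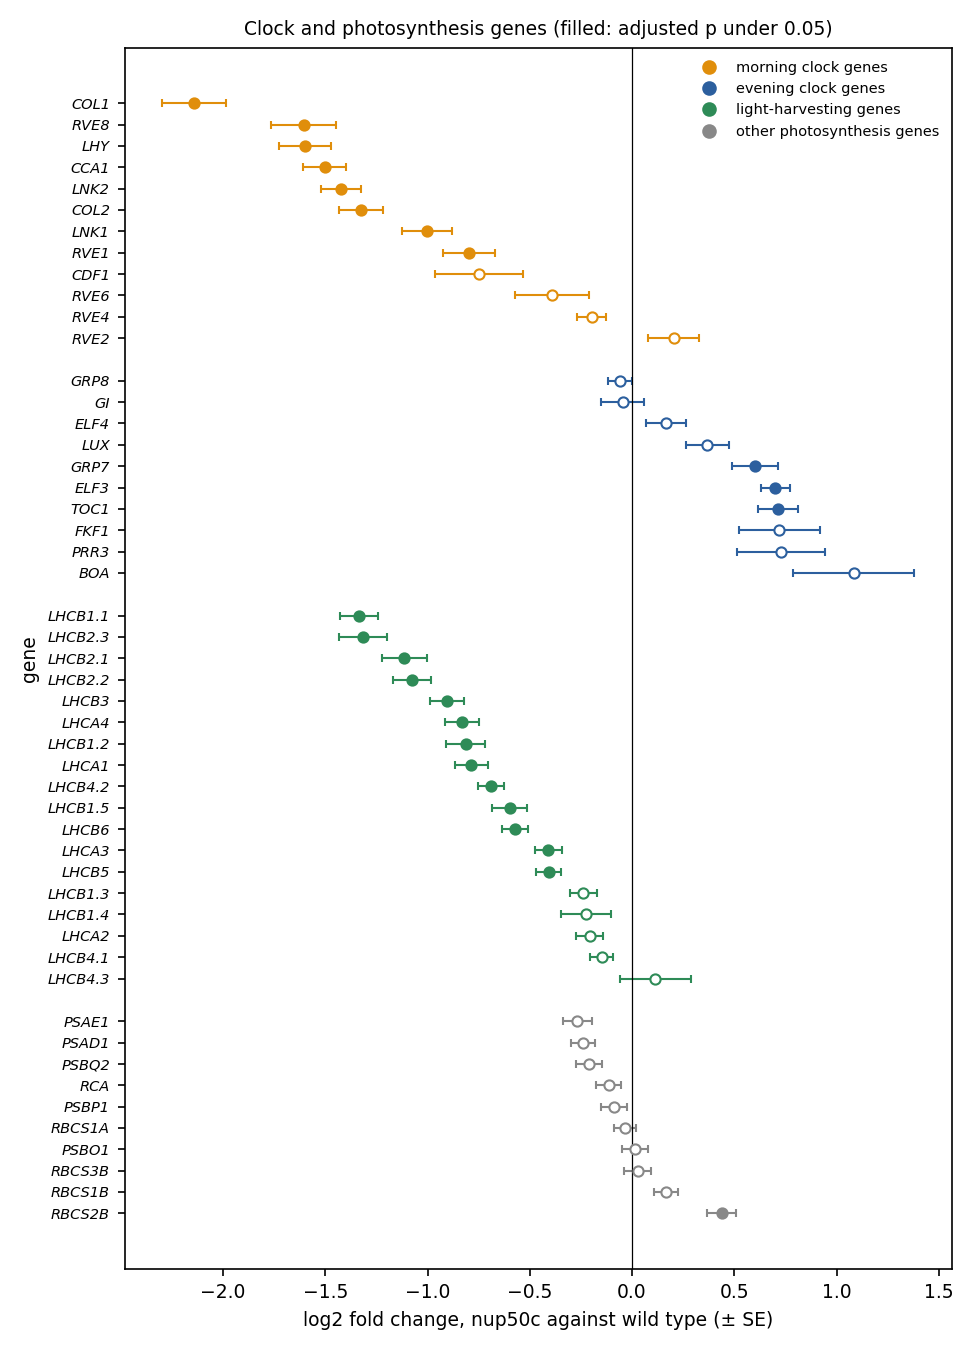
Log2 fold change in nup50c against wild type with its standard error (horizontal axis) for clock genes of the morning and evening phases, light-harvesting genes and other photosynthesis genes (vertical axis, n = 3 libraries per group); filled points passed the edgeR test. Among morning clock genes *COL1* reaches -2.14, while the 10 other photosynthesis genes lie between -0.27 and 0.44; *PRR9*, listed at 0 in wild-type replicate 2, is left out.

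Of 28 measured photosynthesis genes, 13 fell, 1 rose and 14 did not pass the edgeR test. Adjusted over the list alone, 19 fell and 2 rose. The 13 genes encode light-harvesting chlorophyll-binding proteins, of which 18 were measured. *LHCB1.1* went from 4230 ± 258.3 to 1677 ± 216.1 CPM (log2 fold change -1.33, SE 0.09, adjusted p = 0.000833), *LHCB2.2* fell by 1.08 (adjusted p = 0.00208) and *LHCB3* by 0.90 (adjusted p = 0.00209). *RBCS2B*, a small subunit of Rubisco, was the member that rose, by 0.44 (adjusted p = 0.0183). *RBCS1A* had a log2 fold change of -0.04 (adjusted p = 0.81) and *RCA*, Rubisco activase, of -0.11 (adjusted p = 0.41). The list shifted lower by camera (adjusted p = 1.47e-32; adjusted p = 0.29 with an estimated correlation). Reads of the near-identical *LHCB1*, *LHCB2* and *RBCS* copies could be split between them in counting, so single members are uncertain. *LHCB1.3*, the *LHCB1* copy with the most counts, went from 12693 to 10765 CPM and did not pass (log2 fold change -0.24, adjusted p = 0.112). *LHCB1.4* did not pass either (-0.225, adjusted p = 0.416), while *LHCB1.2* (-0.81) and *LHCB1.5* (-0.60) did. The call of *RBCS2B* was lost without wild-type replicate 1 or 2 or nup50c replicate 1 or 2 (highest adjusted p = 0.109), and those of *LHCA3*, *LHCB1.5* and *LHCB5* without wild-type replicate 1 or nup50c replicate 2, among others (highest adjusted p = 0.107, 0.0775 and 0.0789). Among 17 chlorophyll biosynthesis genes, *CAO* (log2 fold change -0.82, adjusted p = 0.00208), *CRD1* (-0.42, 0.0116), *GUN4* (-0.54, 0.0265) and *GUN5* (-0.43, 0.0272) fell, and 4 were lower adjusted over the list alone. *CAO* kept its call without each library, the others did not (highest adjusted p = 0.0698 for *CRD1* without wild-type replicate 1 or nup50c replicate 2, 0.151 for *GUN4*, 0.139 for *GUN5*). The chlorophyll list, with a median of 0.05 and a mean of -0.15, did not pass camera (adjusted p = 0.143) but did with offsets for GC content and length (adjusted p = 0.0299), with DESeq2 (adjusted p = 0.0430) and without wild-type replicate 2 (adjusted p = 0.0333).

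In light signalling, 6 of 23 measured genes fell over all genes tested, and 6 were lower adjusted over the list alone. *ELIP1* (log2 fold change -1.06, adjusted p = 0.00646) and *ELIP2* (-1.64, 0.0105) encode early light-induced proteins of the thylakoid, and *HYH* (-1.18, 0.00804) a homologue of the transcription factor HY5. *BBX24*, *BBX28* and *PIF5* were the other members that fell. The calls of *ELIP2*, *BBX24*, *PIF5* and *BBX28* were lost without wild-type replicate 1 or nup50c replicate 2, among others (highest adjusted p = 0.0612, 0.0693, 0.0927 and 0.0964). The list shifted lower by camera (adjusted p = 1.33e-06; adjusted p = 0.29 with an estimated correlation).

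In the iron homeostasis list, 3 of 26 measured genes fell, and 4 adjusted over the list alone. *FRO2*, the root ferric reductase, went from 26.1 ± 4.60 to 7.04 ± 0.988 CPM (log2 fold change -1.89, SE 0.17, adjusted p = 0.00208). *IRT1*, the main iron uptake transporter, went from 70.5 ± 14.3 to 30.6 ± 1.90 CPM (adjusted p = 0.00775) and *CYP82C4* fell by 2.59 on the log2 scale (adjusted p = 0.00417). The list shifted lower by camera (adjusted p = 2.03e-06, or 0.58 with an estimated correlation), and fry gave it an adjusted p of 0.135. The mean deviation of its genes, 3 of which had a 0 in some library, was 0.20 in nup50c replicate 2. It was -0.46 and -0.71 in the other nup50c libraries. In wild type it was 0.48, 0.47 and 0.02, so nup50c replicate 2 lay above wild-type replicate 3. Of 17 phosphate starvation genes, *PAP17* (log2 fold change -0.65, adjusted p = 0.0219), *SPX1* (-0.62, 0.0397) and the noncoding *AT4* (from 24.9 ± 5.85 to 12.4 ± 1.92 CPM, 0.0330) fell, and 3 were lower adjusted over the list alone. Each of these 3 calls was lost without wild-type replicate 1, nup50c replicate 1 or nup50c replicate 2, among others (highest adjusted p = 0.137, 0.172 and 0.151). That list shifted lower by camera (adjusted p = 0.0110; adjusted p = 0.58 with an estimated correlation), and not without wild-type replicate 3 (adjusted p = 0.0883). In flavonoid and anthocyanin synthesis, all 21 measured genes had log2 fold changes below 0, and 1 passed the edgeR test, *DFR*, dihydroflavonol reductase (-1.06, adjusted p = 0.0253), as did 1 adjusted over the list alone. Of the 21 genes, 2 had a 0 in some library. *DFR* was called without nup50c replicate 1 and lost without any other library (highest adjusted p = 0.112). The flavonoid list shifted lower by camera (adjusted p = 2.03e-06; adjusted p = 0.55 with an estimated correlation).

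Single genes passed the test in lists that did not shift by camera. Of 21 nitrate and nitrogen genes, *BT2* (log2 fold change 0.58, adjusted p = 0.0328) and *NRT1.5* (0.28, 0.0377) rose and *LBD37* (-0.36, 0.0374) fell, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.78). Of 15 senescence and carbon starvation genes, *NYC1*, a chlorophyll b reductase (0.74, 0.00646), and *DIN10* (0.74, 0.0190) rose and *NAP*, a NAC transcription factor (-1.41, 0.0142), fell, with 4 higher and 3 lower adjusted over the list alone. Camera put this list higher (adjusted p = 0.89), while its median was -0.12 and its mean -0.29. *HSP70* (0.50, 0.0448) rose among 15 heat shock genes, with 2 higher adjusted over the list alone (camera upward, adjusted p = 0.43, median 0.04, mean -0.03). *NUP188*, a scaffold nucleoporin (0.36, 0.0323), rose among 32 nuclear pore genes, with 1 higher adjusted over the list alone. The nuclear pore list did not pass camera on the counts (adjusted p = 0.0691) and did in the 3 FPKM settings (adjusted p = 0.0330 to 0.0421). Of these genes *NYC1* kept its call without each library, and the others lost theirs without nup50c replicate 2, among others (highest adjusted p from 0.0925 for *DIN10* to 0.202 for *HSP70*).

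The salicylic acid and immune list had log2 fold changes below 0 in 27 of 30 measured genes, and the touch and early stress list above 0 in 19 of 19, with 0 members of either passing the edgeR test over all genes. A 0 in some library was listed for 6 of the 30 salicylic acid genes and 1 of the 19 touch genes, and these stayed in the list values. Adjusted over the list alone, 5 salicylic acid genes were lower and 3 touch genes higher. *NIMIN2* (log2 fold change -1.91, adjusted p = 0.0634) and *PAD4* (-1.12, 0.0686) had the smallest p in the first list, and *ERF104* (1.04, 0.0816) in the second. By camera the salicylic acid list shifted lower (adjusted p = 5.36e-11; adjusted p = 0.58 with an estimated correlation) and the touch list higher (adjusted p = 9.36e-07; adjusted p = 0.65 with an estimated correlation). The mean deviation of the salicylic acid genes from the average of all libraries was 0.998, 1.4 and 0.09 log2 units in wild type and -0.83, -1.75 and 0.09 in nup50c. For the touch genes it was -0.64, -0.14 and -0.61 in wild type and -0.28, 0.30 and 1.38 in nup50c, highest in nup50c replicate 3, the library apart on the second component. The jasmonate and wound list shifted higher (adjusted p = 0.0152; adjusted p = 0.77 with an estimated correlation) with 0 of 28 genes passing over all genes and 4 higher and 1 lower adjusted over the list alone. This call was lost without nup50c replicate 3 (adjusted p = 0.64), without wild-type replicate 1 (adjusted p = 0.0521) and without wild-type replicate 3 (adjusted p = 0.0798). The mean deviation of the jasmonate genes was -0.246, 0.015 and -0.174 in wild type and -0.514, 0.262 and 0.656 in nup50c. In nup50c replicate 1 it thus lay below each wild-type library.

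Ribosomal protein genes and genes of the organelle genomes gave 0 calls by the edgeR test. The 14 genes described as 60S or 40S ribosomal proteins shifted lower by camera (adjusted p = 0.0171; adjusted p = 0.70 with an estimated correlation), as did 304 other ribosomal protein genes (adjusted p = 0.000478; adjusted p = 0.77 with an estimated correlation), by medians of -0.17 and -0.10. Adjusted over the list alone, 1 gene was lower in the first list and 0 in the second. Both ribosomal calls were lost without nup50c replicate 3 (adjusted p = 0.233 and 0.398), without wild-type replicate 3 (0.0798 and 0.0542) and with offsets for GC content and length (0.149 and 0.332). The 25 mitochondrion-encoded genes tested, of 112, shifted lower by camera (adjusted p = 0.0251, or 0.58 with an estimated correlation). The 61 plastid-encoded genes tested, of 108, shifted higher (adjusted p = 0.0410, or 0.77 with an estimated correlation). Each list had 0 genes adjusted over the list alone. Mitochondrion-encoded genes held only 0.0143% to 0.0171% of a library's counts and plastid-encoded genes 0.0735% to 0.1046%, so both shifts rest on traces. The mitochondrial call was lost without nup50c replicate 3 (adjusted p = 0.296), without wild-type replicate 3 (0.162), with DESeq2 (0.126), without a filter (0.0981), with at least 10 counts in all libraries (0.260) and over genes above 0 in all libraries (0.0579). The plastid call was lost without wild-type replicate 1 (adjusted p = 0.105), wild-type replicate 2 (0.185), nup50c replicate 1 (0.315) or nup50c replicate 2 (0.17), with DESeq2 (0.126) and without a filter (0.0502).

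Among called genes above 0 in every library, with at least 1 CPM in the higher group and no overlap between the groups, the largest fitted rises were those of AT3G28290 and AT3G28300, near-identical copies annotated as *AT14A*, between which reads could be split in counting. They lie on chromosome 3 of TAIR10.1 from 10547441 to 10549401 and from 10565674 to 10567634. AT3G28290 went from 6.86 ± 1.07 to 36.8 ± 4.89 CPM (log2 fold change 2.42, SE 0.15, edgeR adjusted p = 0.000729), and AT3G28300 rose by 2.41. AT5G51190, encoding a DNA-binding protein, rose by 2.14 (adjusted p = 0.0318) and AT3G22125 by 1.94 (adjusted p = 0.00920). The largest fitted falls among the same called genes were those of *GSTU4*, a glutathione transferase (-3.27, adjusted p = 0.0428), AT3G47480, encoding a calcium-binding protein (-3.17, 0.00300), AT1G76960 (-2.82, 0.0392) and AT3G28540 (-2.68, 0.00299). The call of AT3G22125 was lost without wild-type replicate 1 (adjusted p = 0.0602), and those of AT5G51190, *GSTU4* and AT1G76960 without wild-type replicate 1 or 2 or nup50c replicate 1, among others (highest adjusted p = 0.176, 0.152 and 0.150).

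By the same rule without the limit to genes above 0, the 8 largest fitted rises were of genes listed at 0 in all wild-type libraries, and the 12 largest fitted falls of genes listed at 0 in all nup50c libraries. *CBF1*, a transcription factor of the cold response, had 45, 57 and 139 counts in nup50c (adjusted p = 0.0154), a call lost without wild-type replicate 1, nup50c replicate 2 or nup50c replicate 3 (highest adjusted p = 0.0694). *ASY1*, a protein of meiotic chromosome axes, had 123, 84 and 48 counts in nup50c (adjusted p = 0.00984), a call lost without nup50c replicate 1 or 2 (highest adjusted p = 0.0575), and the noncoding AT2G05695 had 98, 105 and 94 (adjusted p = 0.00532). The others listed at 0 in wild type were AT3G09550, AT1G61610, AT5G08480, AT3G54160 and AT4G03130. Leaving out any 1 library lost the calls of AT5G08480, AT3G54160 and AT4G03130 (highest adjusted p = 0.114). Those of AT3G09550 and AT1G61610 held only without wild-type replicate 3 (highest adjusted p = 0.0776 and 0.0945). *GPT2*, a plastid glucose-phosphate translocator, had 195, 314 and 142 counts in wild type (adjusted p = 0.00289), and *TPS04*, a terpene synthase, 141, 192 and 203 (adjusted p = 0.00191). *CKX1*, a cytokinin oxidase, had 84, 107 and 216 counts in wild type and was listed at 0 in nup50c (adjusted p = 0.00555), where its FPKM were 2.03, 2.41 and 1.68 against 1.76, 2.75 and 2.74 in wild type. *NRT2.5*, *CSLG2*, *CRK15*, *GPCR*, AT2G04495, AT4G10860, AT1G64625, AT1G76470 and AT5G22530 were the remaining genes listed at 0 in nup50c. Each of these remaining genes lost its call without wild-type replicate 1 or 2, and some without other libraries too. Their highest adjusted p ran from 0.0756 for AT1G64625 to 0.176 for AT4G10860. The FPKM table also went against some of the other zeros. In nup50c it gave *GPT2* 0.439, 0 and 1.1 (2.92, 4.58 and 1.88 in wild type) and AT1G64625 0.993, 1.5 and 0 (1.14, 1.21 and 1.17 in wild type). In wild type it gave AT3G09550 0.655, 0 and 0.671 (0.496, 1.13 and 0.850 in nup50c), AT1G61610 0.408 in replicate 2 and AT5G08480 0.452 in replicate 3. The table also lists 654 genes at 0 in exactly 1 library, so a 0 can be a failed estimate, and no fold is given for these genes. In the cold response list, *CBF1* was the 1 member of 9 to pass, also 1 adjusted over the list alone. That list did not pass camera (adjusted p = 0.0987) but did with offsets for GC content and length (adjusted p = 0.0190) and without nup50c replicate 1 (adjusted p = 0.0329).

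Of the 21158 genes, 4943 (23.4%) had values that did not overlap between the groups, where chance gives 10% on average for 3 against 3. Genes that vary together can take this share far from 10% by chance, and it was not computed for other splits. The fullest window of 100 consecutive tested genes held 10 called genes, against a median of 8 in 10000 permutations (one-sided permutation p = 0.126). Of 92 named genes that passed, 36 did so in all 6 fits leaving out 1 library. These 36 include AT2G05695, *GPT2*, *TPS04* and *CKX1*, which are listed at 0 throughout one group. Many named genes were picked for a small p or a large change. Without wild-type replicate 1, 37 of the 92 kept their call, and 102 of all 483 called genes did. On simulated data 11.9% of the calls were false, above the 5% aimed at.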

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

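*CBF2*, a cold-response transcription factor, lay outside the main test: it was the 1 gene to pass among the 1968 that only the FPKM table holds, of which 937 were above 0 in some library. Over all 23552 genes the same FPKM setting called 233 higher and 255 lower, a larger share than 1 of 937. Its FPKM were 1.06, 0.756 and 0.843 in wild type and 2.18, 2.85 and 4.76 in nup50c, higher in each mutant library than in each wild-type library. The difference was 1.14 on the log2(FPKM + 1) scale (limma adjusted p = 0.0408), a scale that understates changes of low genes. The related *CBF1* had an FPKM of 0 in the 3 wild-type libraries and of 0.968, 1.15 and 3.14 in nup50c. How reads shared by these similar genes were counted is not given in the sources used here.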

How the results depend on the processing

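The offsets for GC content and length, the restriction to genes above 0 in all libraries and the position counts under other settings were chosen after the data were seen. The fall of *NUP50C* kept its direction and passed in every setting run, with log2 fold changes from -1.64 to -1.34 (adjusted p up to 0.0265). The main counts were 236 genes higher and 247 lower. At least 10 counts in all libraries gave 394 and 378, genes above 0 in all libraries 398 and 380, and DESeq2 662 and 616; the cause was not tested. A 2-fold minimum gave 28 and 93 by construction, with 8 and 24 of them listed at 0 throughout one group. Leaving out 1 library gave 43 to 172 higher and 65 to 266 lower, with fewer samples. The replicate number as a block gave 12 and 19, of which 30 were called without it, and took the plastid list's adjusted p to 0.0516. Same-numbered samples had correlations of deviations of -0.031, -0.123 and -0.098, none its sample's best. These values give no sign of pairing, but 3 samples per group are too few to exclude a pairing or batch. All 483 called genes kept their sign in each setting that tested them. RLE factors, other library sizes, no filter, the FPKM settings and the GC and length offsets stayed within 1.5 times of the main counts. Camera called 14 lists at its preset correlation and 0 with the correlation estimated from the data. For those 14 the estimates lay above the preset, from 0.018 (circadian clock) to 0.777 (touch). With the estimate, camera also takes its degrees of freedom from the 6 libraries instead of the genes. The lost calls therefore cannot be put down to the correlation alone, least of all for the clock list. Fry, which tests each list against no change, called 5. These were photosynthesis, light signalling, circadian clock, stomata and the NUP50 and RanBP1 family, whose 1 called member is *NUP50C* itself. Fry did not call the salicylic acid (adjusted p = 0.234), touch (0.318), iron (0.135) or flavonoid (0.117) lists. Leaving out 1 library gave 9 to 15 camera calls, with 9 without wild-type replicate 3 and 9 without nup50c replicate 3. The position p stayed between 0.13 and 0.92, with 3 to 16 called genes in the fullest window. Of 92 called named genes, 92 stayed called with DESeq2, 85 with the GC and length offsets, 73 on log2(FPKM + 1) and 19 with the block. No depth limit was derived for genes listed at 0, since what sets these values was not settled.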

Other observations

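The tests of clock phase, of the share of leaf tissue and of genes listed at 0, the offsets for GC content and length and the restriction to genes above 0 were chosen after the data were seen. Growth hormone and tissue lists held 0 called genes. The edgeR test passed 0 measured genes of the auxin (31), cytokinin (15), gibberellin and brassinosteroid (25), ethylene (14) and abscisic acid and dehydration (19) lists, over all genes and adjusted over the list alone. Their camera adjusted p was 0.143, 0.78, 0.30, 0.78 and 0.42. The auxin list did pass without wild-type replicate 3 (adjusted p = 0.0160, mean -0.50), with at least 10 counts in all libraries (0.0429), over genes above 0 in all libraries (0.0435) and on log2(FPKM + 1) without a filter (0.0480). The marker lists of stomata (0.42), vasculature (0.78), root tissues (0.78) and root hairs (0.89) did not pass camera either, with 0 members called by either adjustment, and fry gave the stomatal list an adjusted p of 0.0427 at a median log2 fold change of -0.16.

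Nuclear transport receptors and Ran (camera adjusted p = 0.42) had 1 gene higher adjusted over the list alone and 0 over all genes, and glucosinolate metabolism (0.27) had 1 higher and 3 lower against 0. Both counts were 0 for mRNA export and miRNA processing (0.998), flowering time (0.78), cell cycle and DNA replication (0.93), DNA damage (0.93), the unfolded protein response (0.93), low oxygen (0.26), and expansins and xyloglucan hydrolases (0.75). The low-oxygen list passed without wild-type replicate 2 (adjusted p = 0.0333) and without nup50c replicate 2 (0.0261). Median and mean differed in sign for ethylene (-0.08 and 0.02), DNA damage (0.01 and -0.10), root tissues (0.01 and -0.00) and mRNA export (-0.02 and 0.03). *COR27*, a cold- and clock-regulated gene, rose from 10.3 ± 2.43 to 23.7 ± 1.25 CPM (SD, n = 3 each, edgeR adjusted p = 0.00951), a call lost without wild-type replicate 1 or nup50c replicate 2 (highest adjusted p = 0.0638).

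Morning genes of the clock list, by textbook phases assigned after these values were seen, were below 0 in 11 of 13 and evening genes above 0 in 8 of 10, with medians differing by 1.65, and the mean deviation of morning genes was 0.66, 0.40 and 0.51 in wild type and -0.49, -0.59 and -0.48 in nup50c. GC content and gene length as the whole cause are argued against by a fit with offsets for both, in which the called morning genes had a median of -1.53 (-1.46 before) and all 8 stayed called. A smaller share of leaf tissue as the whole cause would lower leaf-borne transcripts alike, and is argued against by the 10 other photosynthesis genes, whose median was -0.06 (range -0.27 to 0.44), 0.58 above the -0.64 of the light-harvesting genes. A difference in time of day or clock phase at harvest remains a hypothesis that these genes cannot test, since they are the genes that prompted it. Harvest times are not given in the sources used here, so a different harvest time of the groups and an effect of the genotype on the clock both stay open. The same limit applies to the other genes and lists compared here, which come from the same libraries.

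For the 32 called genes listed at 0 throughout one group, 7 (21.9%) had an FPKM above 0 in that group, *CKX1* and *GPT2* among them, which leaves failed estimates open for the set. Their median coverage in the other group (counts times the read length of 150 nt over exonic length) was 5.33, which is 1.29 times the 5th percentile of all coverages above 0, a ratio computed after such values had been seen, so a coverage minimum below which the table gives 0 stays open too. A level just under such a minimum and a true absence could both be listed this way. On log2(FPKM + 1) 8 of the 32 passed.

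Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the 483 of the real split, the real one itself, and the highest of the others gave 2. The splits are too few for a share under 0.05. The fullest window of called genes (AT2G03975 to AT2G05695) held 10, which equals the 95th percentile of the permuted maxima, at a permutation p of 0.126. A p of 0.05 or more had been set beforehand to exclude a segment of another background or an insertion carried with the mutation. That bound was wrong, because a small segment can add too few called genes to pass the maximum over all windows, so such a segment stays open. Around *NUP50C*, 1 of the 100 nearest tested genes was called, where 2.29 would be expected from the genome-wide share.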
